A study of Drosophila melanogaster with 4 samples.

How the data were processed

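ChIP DNA and input DNA from Oregon-R larvae of the third instar were sequenced, with 2 libraries of each kind. Per the labels' protocols, homogenized tissue was fixed with formaldehyde, nuclei were opened with SDS and sonication, and chromatin bound by the antibody was collected on beads. Bowtie 0.12.7 is named in the submitters' processing notes; its settings, including the treatment of reads that map to several places, are not given in the sources used here. The deposited files are lists of significantly enriched regions on FlyBase release 5, per the file headers. Each region has a first and a last base and a score, which the authors assigned, and neither its scale nor its log base is named in the files. The region caller, its threshold, and how the input libraries and the 2 replicates entered the combined list are not given in the sources used here. Lists were called per ChIP library for replicates 1 and 2 and once for the replicate set, as deposited. The shortest region is 1301 bp in both replicate lists and 1001 bp in the combined list (383 regions of exactly that length), so the combined list was made with another minimum.

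Groups and replicate numbers follow the sample titles. No list of an input library was used here, so no region was compared with its input directly. Nothing in the labels says whether the 2 ChIP libraries came from separate collections of larvae, so the spread between them may be technical. The p-values rest on arms, positions or regions of these lists and do not measure the spread between libraries. Read depth is not recorded in the lists and no read counts were inferred. The 5 depleted regions of the combined list were left out of all comparisons. The last region of the combined list on 3RHet ends 237 bp beyond the length given in the file header and was counted up to that length in covered shares. The sequence Uextra, named in the headers, carried no region and was left out.

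Covered shares are bases inside regions over the arm length in the file headers, given as mean ± SD over 2 replicates. Het sequences and large arms were compared by exact permutation of arm labels, proximal and remaining parts of arms by exact sign flips over 5 arms, and replicate lists by the Jaccard index against 100000 circular shifts within each arm on a grid of 50 bp. Median scores were compared by permutation with 100000 resamples, over all regions and, as a later addition, within 18 strata (each arm, with the large arms split at the proximal 2 Mb). P-values were adjusted by the Benjamini-Hochberg method over the 5 planned tests. A region counted as shared when at least 1 bp overlapped the other list. Shares of regions carry 95% Wilson intervals, which cover counting error only; neighbouring regions are not independent. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

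The tests were checked on simulated lists. With 10048 regions placed at random, the shift test called 1 of 40 runs at 0.05, and it called 40 of 40 when 500 regions were copied from the other list. The random placement did not keep the clustering of the real list. This check therefore does not cover lists that share broad clustering without sharing positions. With shuffled scores the median test called 1 of 40 runs, and 40 of 40 when 3000 scores were raised by 0.05. The test within strata called 1 of 40 runs with scores shuffled within strata, and 40 of 40 when the 3769 shared regions were raised by 0.05.

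Comparisons, tests and alternatives were fixed before the data were examined, except where stated. The regions named in the text are the 5 longest stretches called in both replicates on chromosome 4, on the Het sequences and on the large arms, by a rule also fixed then; windows of 100 kb were added later. Planned tests of start sites and of gene lists, and values of named genes, were not run: the gene table at hand is of release 6, and coordinates were not converted between releases. Alternatives covered the top 50% by score, the longest 50%, merging of regions less than 1 kb apart, stricter overlap, other proximal windows, regions per Mb, arm subsets, each replicate alone and the combined list.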

Results

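Binding of Su(var)3-9 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in larvae of the third instar of the wild-type Oregon-R strain of Drosophila melanogaster. Su(var)3-9 is a histone methyltransferase that modifies histone H3 in heterochromatin, the compact and repeat-rich part of the genome around the centromeres. The affinity-purified rabbit antibody Q2598 was raised against residues 320 to 419 of the protein. The series holds 4 libraries, 2 from ChIP DNA and 2 from input DNA, and the files analysed here are region lists of the 2 ChIP libraries plus a combined list for the replicate set. The list of ChIP replicate 1 held 6699 enriched regions covering 16.0 Mb, and that of replicate 2 held 10048 regions covering 21.4 Mb. The combined list held 21932 enriched regions covering 44.2 Mb. All coordinates are FlyBase release 5, in which 2L, 2R, 3L, 3R and X are the large, mostly euchromatic arms, the 6 sequences ending in Het hold pericentric and Y heterochromatin, and U holds scaffolds not placed on any arm. Read depth is unknown, because the lists carry no counts, so intervals below cover only the number of regions. Enrichment scores are the authors' own value per region.

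In both replicates enriched regions were concentrated in pericentric heterochromatin. They covered 35.2% ± 6.00 (SD, n = 2) of the combined length of the Het sequences and 11.3% ± 4.00 (SD, n = 2) of the large arms. Sequence 3LHet was the most heavily covered, at 42.8% ± 7.60 (SD, n = 2), followed by 3RHet at 37.1% ± 4.77, 2RHet at 32.0% ± 6.77, 2LHet at 27.7% ± 4.18 and XHet at 25.7% ± 0.222. YHet, which holds fragments of the Y chromosome, stood apart from the other Het sequences at 9.49% ± 1.33 (SD, n = 2). Its few regions, 18 in replicate 1 and 11 in replicate 2, nevertheless had the highest median scores of any sequence, 1.57 and 1.69. Among the large arms coverage ran from 9.17% ± 4.37 on X to 15.4% ± 5.37 on 2R. The difference between the mean of the 6 Het sequences, 29.1% ± 11.5 (SD over arms), and the mean of the 5 large arms, 11.4% ± 2.40, was 17.7 percentage points. An exact two-sided permutation of the 462 assignments of arms to the Het and large classes gave p = 0.0152, or 0.0189 after Benjamini-Hochberg adjustment over the 5 planned tests. Arms are not independent samples, so this p describes the 2 libraries. In the combined list the difference was 12.0 points (exact p = 0.0779), and counted as regions per Mb in the replicate lists it was 28.6 (exact p = 0.0519).

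**Figure D1:**
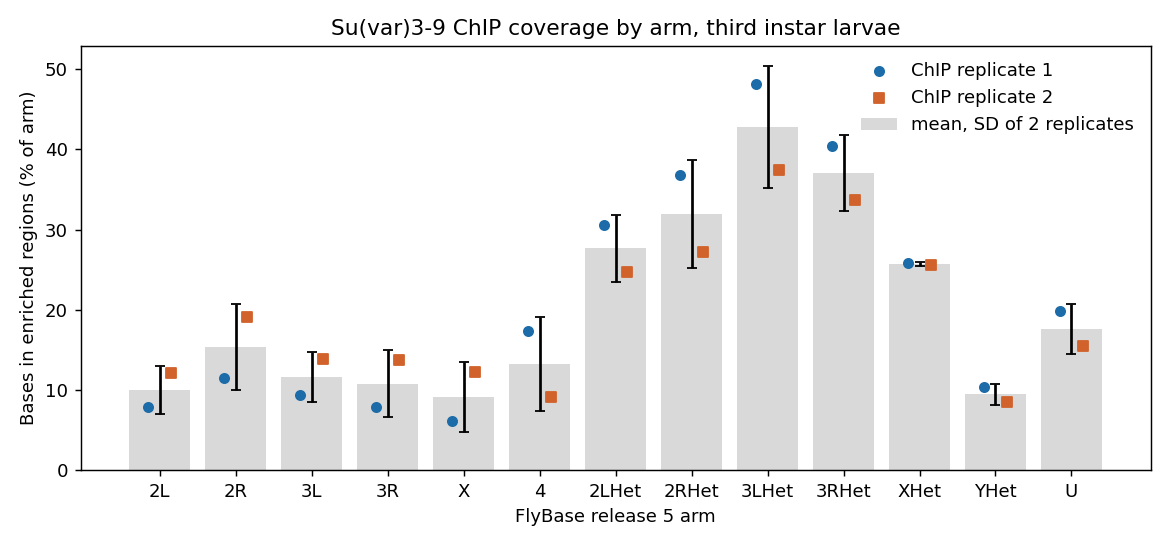
Bases inside enriched regions as a percentage of each FlyBase release 5 sequence. Bars are the mean and error bars the SD of 2 ChIP replicates, circles are replicate 1 and squares replicate 2; in both replicates the 5 Het sequences other than YHet lie above all large arms.

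The heterochromatic excess was present in each library but differed in size. In replicate 1 the Het sequences were covered at 39.4% and the large arms at 8.49%, a ratio of 4.64. In replicate 2 the Het sequences were covered at 30.9% and the large arms at 14.1%, a ratio of 2.19. Regions on the Het sequences were also longer, with a median of 2689 bp in replicate 1 and 2348 bp in replicate 2, against 1710 bp and 1677 bp on the large arms. Their median score was 1.15 in replicate 1 and 0.853 in replicate 2, against 0.620 and 0.531 on the large arms. The longest stretches called in both replicates on the Het sequences measured 30042 bp on 2RHet (3019316 to 3049357), 22837 bp on 3LHet (1401241 to 1424077), 19124 bp on 2RHet (143276 to 162399), 18466 bp on 3RHet (1945208 to 1963673) and 17534 bp on 3RHet (1637256 to 1654789). The 3RHet stretch of 17534 bp had the highest scores of these, 2.21 in replicate 1 and 1.64 in replicate 2.

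Enriched regions were also dense at the centromere-proximal ends of 3 of the 5 large arms. In the proximal 2 Mb, coverage reached 41.3% ± 3.84 (SD, n = 2) on 2R, 37.5% ± 4.61 on 3L and 21.8% ± 2.68 on 2L, against 12.6% ± 6.33, 9.34% ± 3.84 and 8.88% ± 3.57 over the rest of those arms. On 3R the proximal value was 11.1% ± 3.71 against 10.8% ± 4.23 over the rest, and on X it was 9.09% ± 1.63 against 9.18% ± 4.63, differences smaller than the spread between the replicates. Averaged over the 5 arms the proximal excess was 14.0 percentage points, with an exact two-sided sign-flip permutation p = 0.125 (0.125 after Benjamini-Hochberg adjustment). With 5 arms the smallest p this test can give is 0.062.

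Windows of 100 kb showed where on the arms the dense blocks lay. Of 1194 windows on the large arms, 36 had at least 25% of their bases inside regions of both lists at once. All 36 lay among the 103 windows that touch the proximal 2 Mb. The windows and the 25% limit were not fixed in advance, and the highest window elsewhere, on 2L, reached 21.9%. Of the 36 windows, arm 2R held 14, 3L held 13, 2L held 8, X held 1 and 3R held 0. The densest window of 2R (900001 to 1000000) was covered at 78.6% in replicate 1 and 68.0% in replicate 2. The densest of 2L (22500001 to 22600000) was covered at 71.3% and 53.7%, and the densest of 3L (23400001 to 23500000) at 67.0% and 54.0%. The single dense window of X (21600001 to 21700000) was covered at 40.9% and 36.4%. The 5 longest stretches called in both replicates on the large arms fell within these ends. They measured 22694 bp on 3L (23288675 to 23311368), 18059 bp on 2L (22479944 to 22498002), and 15934, 15128 and 13561 bp on 2R (starting at 412662, 1454374 and 465595).

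**Figure D2:**
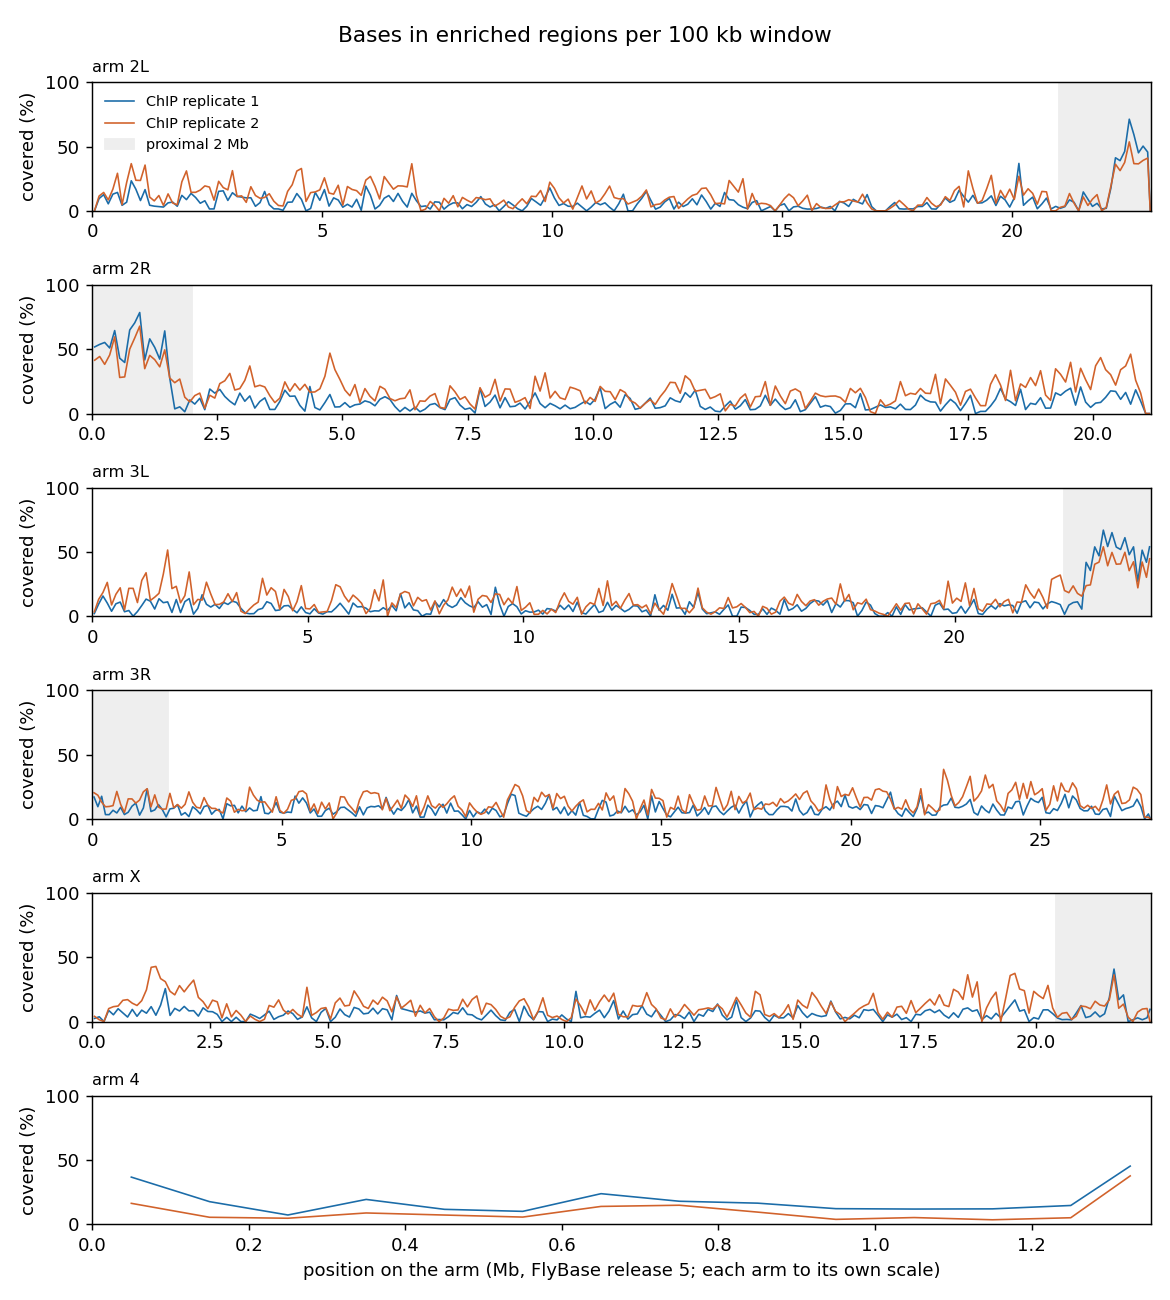
Percentage of each 100 kb window inside enriched regions along 2L, 2R, 3L, 3R, X and chromosome 4 (position in Mb, FlyBase release 5), with 1 line per ChIP replicate and the centromere-proximal 2 Mb of the large arms shaded. Both replicates rise in the shaded ends of 2L, 2R and 3L and not along 3R, and replicate 2 lies above replicate 1 over much of the remaining arms.

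Chromosome 4, a small chromosome with interspersed heterochromatin and active genes, gave opposite results in the 2 replicates. It was covered at 17.3% in replicate 1, 2.04 times the value of the large arms, and at 9.10% in replicate 2, 0.643 times that value. The log2 ratio of the mean coverages was 0.22, with an SD of 1.18 between the replicates, a ratio smaller than that spread. It was not tested. Bases called in both lists made up 7.06% of chromosome 4 and 3.72% of the large arms, a difference also not tested. Both replicates had their highest coverage at the ends of chromosome 4. The last window (1300001 to 1351857) was covered at 45.2% and 37.6%, and the first (1 to 100000) at 36.7% and 16.3%. The longest stretches in both lists lay at 12987 to 24471 (11485 bp, scores 2.11 and 1.61) and at 778801 to 787992 (9192 bp, scores 0.857 and 0.688), followed by stretches at 10 to 4681, 623822 to 627613 and 1325869 to 1329576.

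The 2 replicate lists were compared to ask which regions were called in both. A larger share of heterochromatic than of euchromatic regions had a partner, without allowance for their greater length and coverage, which raise overlap by chance. On the Het sequences 74.0% of the 955 replicate 1 regions overlapped a replicate 2 region (95% Wilson interval 71.2 to 76.7), and 90.1% of the 847 replicate 2 regions overlapped a replicate 1 region (87.9 to 91.9). On the large arms the same shares were 48.5% of 4923 (47.1 to 49.9) and 29.3% of 8524 (28.3 to 30.3). On chromosome 4, 37 of 88 regions (95% Wilson interval 32.3 to 52.5%) and 38 of 49 regions (64.1 to 87.0%) had a partner.

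Measured in bases, the lists shared 8.17 Mb, a Jaccard index (shared bases over bases in either list) of 0.280, against a mean of 0.0867 when one list was shifted at random within each arm. The index was 0.630 on the Het sequences (0.220 when shifted, a ratio of 2.87) and 0.197 on the large arms (0.0579, a ratio of 3.40). The index was 0.364 on chromosome 4 (0.0639) and 0.546 in the proximal 2 Mb of the large arms (0.185). Over the rest of the large arms it was 0.141 (0.0487, a ratio of 2.88). An index has an upper limit, which caps the ratio more where the shifted value is high. The ratios therefore do not rank the Het sequences against the large arms, and their difference was not tested. The one-sided permutation p was 1e-05 for the whole genome, the smallest that 100000 draws can give, and 1.67e-05 after adjustment over the 5 planned tests. For each of the 7 arm sets examined the adjusted permutation p was at most 0.00012. On the large arms outside the proximal 2 Mb the index lay above the highest shifted value, 0.0695. There 25.4% of the replicate 2 regions had a partner in replicate 1, and 45.1% of the replicate 1 regions had a partner in replicate 2.

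Over all arms, regions called in both replicates had higher median scores than regions called in 1, and much of this followed the arms they lie on. In replicate 1 the median was 0.783 for 3581 shared regions and 0.619 for 3118 others, a difference of 0.163 (two-sided permutation p = 1e-05, 1.67e-05 adjusted). In replicate 2 it was 0.605 for 3769 shared regions and 0.532 for 6279 others, a difference of 0.0728 (permutation p = 1e-05, 1.67e-05 adjusted). Both p-values are the smallest that the draws can give. Permuting scores within each arm, with the large arms split at the proximal 2 Mb, gave a mean difference from the mix of arms alone of 0.0731 in replicate 1 and 0.0592 in replicate 2. That left 0.0904 and 0.0137 (permutation p = 1e-05 for each, again the smallest possible), a comparison added after the data were seen. Region length was not held fixed in these comparisons. Greater length raises overlap by chance, and its part in the differences was not tested. Within the large arms alone the differences were 0.0709 and 0.0130, and in the unplaced scaffolds of U they had the opposite sign, −0.119 in replicate 1 and −0.537 in replicate 2. Within the Het sequences the difference was 0.188 in replicate 1 and −0.0486 in replicate 2 (permutation p = 0.283).

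**Figure D3:**
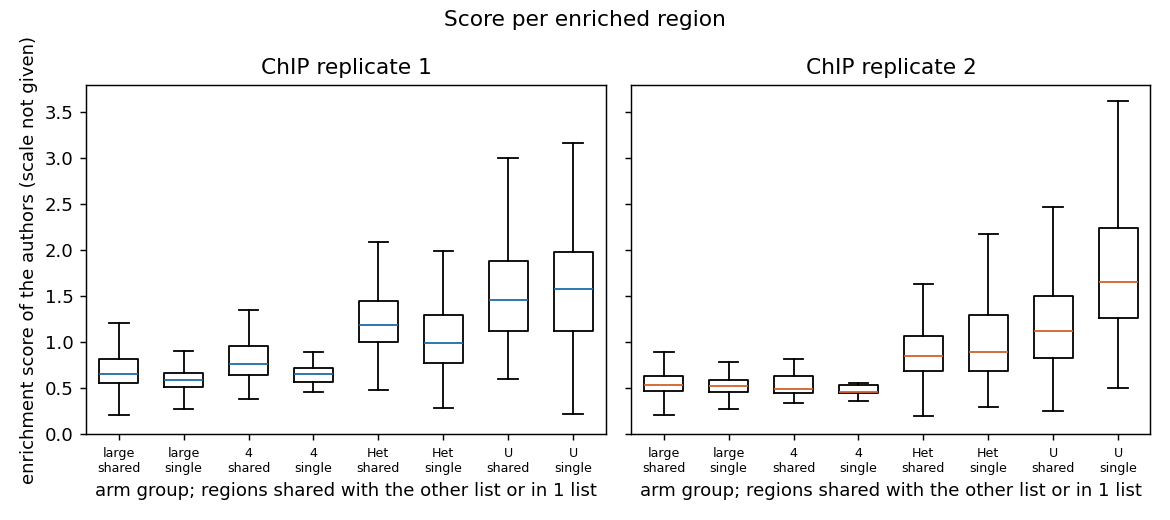
Enrichment score per region, as given by the authors on a scale the files do not name, for regions shared with the other replicate list and regions in 1 list only, by arm group (large arms, chromosome 4, Het sequences, U). Boxes show the median and quartiles, whiskers reach at most 1.5 interquartile ranges and points beyond are not drawn; the single-list regions of U in replicate 2 have a median of 1.66 against 1.12 for shared ones.

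The combined list covered more of both kinds of sequence than either replicate list. It covered 49.5% of the Het sequences and 30.2% of the large arms, a ratio of 1.64, against 4.64 in replicate 1 and 2.19 in replicate 2. As a difference between arm means, its 12.0 percentage points lay close to the 11.9 of replicate 2 alone and below the 23.5 of replicate 1 alone. It contained 91.8% of the bases of the replicate 1 list and 94.5% of those of replicate 2. Of its 21932 regions, 44.4% (95% Wilson interval 43.8 to 45.1) overlapped neither replicate list. That share was 46.3% on the large arms (45.6 to 47.0) and 23.2% on the Het sequences (20.9 to 25.7). On the large arms, combined regions outside both lists had a median score of 0.380, against 0.392 for the others. The medians were 0.748 and 0.786 on the Het sequences and 0.344 and 0.377 on chromosome 4. On U the order was the opposite, at 1.39 outside both lists and 1.10 for the others, with 36.2% of its regions outside (95% Wilson interval 33.6 to 38.9). These differences were not tested. The combined list derives from the same libraries, so its overlap with the replicate lists is no independent check.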

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

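The tests of explanations for the scores on U, and the score comparison within U itself, were chosen after the data were seen. The combined list names 5 depleted regions outside the measurement the comparisons use, on 3L (4552820 to 4554510 and 9497481 to 9499243), 2R (2058253 to 2059961), 2L (10755624 to 10756887) and X (6754865 to 6756466), with scores from −0.129 to −0.00213. Neither replicate list names any.

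The unplaced scaffolds of U, which enter no comparison between arms, were covered at 17.7% ± 3.11 (SD, n = 2), above the 11.3% of the large arms, and no input list was used as a control. Their regions had the highest median scores of any arm group, 1.49 in replicate 1 and 1.23 in replicate 2. In replicate 2 the 158 U regions missing from replicate 1 had a median score of 1.66 against 1.12 for the 470 shared ones, a difference of −0.537 (permutation p = 1e-05, the smallest the draws can give), while in replicate 1 it was −0.119 (permutation p = 0.103). Region length does not account for it, since single-list regions had the higher median in all 4 length classes of equal size, though the longest class held 8 of them. The 5 windows of 100 kb richest in single-list regions held 24 of the 158. Without them the difference was −0.543 (bootstrap 95% interval −0.787 to −0.369), so those windows alone do not account for it. U joins unplaced scaffolds, so windows along it cannot test for related sequence spread over many scaffolds. Repeated sequence that draws reads differently in each library may contribute and was not testable from region lists, and no biological explanation was tested.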

How the results depend on the processing

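Alternatives restricted to the distal large arms, to Het or U regions or to 2L, 2R and 3L, and permutation of scores within arms, were chosen after seeing the data. Of 40 alternatives, 26 kept the direction and, where a p-value was computed, the side of the threshold. Alternatives for shares of regions had no test and were not counted as kept. The 26 include all 6 for the agreement of the replicate lists (Jaccard index 0.141 to 0.614) and all 7 for the proximal excess. For the proximal excess 5 arms or fewer cannot pass the threshold, so those 7 say nothing about stability. The Het excess kept its direction in each alternative run. It missed the threshold in the combined list (12.0 percentage points) and as regions per Mb of the replicate lists (28.6), and the cause was not tested. Regions per Mb of the combined list were not among the alternatives. There the order was the opposite, with 127 on the Het sequences and 163 on the large arms. The excess in covered share was 23.5 points in replicate 1 alone and 11.9 in replicate 2 alone. The log2 ratio of chromosome 4 to the large arms was −0.64 without replicate 1 and 1.03 without replicate 2, against 0.22 as reported. It was 0.47 in the top 50% by score, −0.38 in the combined list and −0.16 as regions per Mb. The causes of these latter changes were not tested. The score advantage of shared regions turned to −0.119 for U in replicate 1, to −0.537 for U in replicate 2 and to −0.0486 for Het sequences in replicate 2 (permutation p = 0.283); elsewhere it was positive, at 0.0904 and 0.0137 within arms. The share of combined regions outside both lists moved to 46.3% on the large arms and 39.0% in the top 50% by score. Requiring overlap of 50% of both regions lowered the shared portion from 53.5% to 38.6% in replicate 1 and from 37.5% to 25.8% in replicate 2. No paired analysis was possible because only the ChIP libraries have lists here. Arm lengths without N bases, start sites and gene lists were not run. Unknown depth limits what the absence of a region in 1 list can show.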

Other observations

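The window picks and all tests below were chosen after the data were seen. Away from the proximal 2 Mb, the windows of 100 kb with most bases in both lists were 2L 20100001 to 20200000 (36.9% in replicate 1 and 26.9% in replicate 2) and 2L 800001 to 900000 (23.4% and 36.7%). They were followed by 3L 9300001 to 9400000 (22.5% and 17.4%), 2R 18500001 to 18600000 (18.9% and 23.0%) and X 6400001 to 6500000 (20.3% and 19.3%). In the first of these 21.9% of the bases lay in regions of both lists at once, below the 25% reached by 36 proximal windows.

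Where regions of the 2 lists overlapped, their scores were positively correlated, with the weakest rank correlation on the large arms. Across 827 overlapping pairs on the Het sequences Spearman's rho was 0.66 and Pearson's r 0.70, across 2591 pairs on the large arms 0.44 and 0.70, and across 41 pairs on chromosome 4 0.77 and 0.88. All permutation p-values over 5 arm sets were 0.0001, the smallest that 10000 permutations can give, and 0.0001 after adjustment. Pairs are across regions, which are not independent replicates.

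Replicate 2 placed 84.8% of its regions on the large arms and replicate 1 placed 73.5%. Of the 6699 highest-scoring replicate 2 regions, 78.6% (95% Wilson interval 77.6 to 79.6) lay on the large arms. That was above the 72.4 to 74.5 of replicate 1, though below the 84.8% of the full replicate 2 list. The threshold of the region caller is not given, so a cut by score need not keep the regions of a shorter call. The cut therefore cannot decide how far the longer list matters. Whether the unmatched regions are placed at random stays open: outside the proximal 2 Mb the Jaccard index was 0.141, above the highest shifted value of 0.0695, but it rests on the 25.4% of replicate 2 regions there that had a partner. A candidate explanation that its test left standing is a smaller heterochromatin contrast in replicate 2, where the median score difference from replicate 1 over overlapping regions was −0.338 on the Het sequences and −0.144 on the large arms (difference −0.194, bootstrap 95% interval −0.216 to −0.175). A plain rescaling of scores between the lists would give the same sign, so this stays open, and no biological explanation was tested, because both libraries belong to 1 group.

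Chromosome 4 stood above the large arms in replicate 1 (log2 ratio 1.03, bootstrap 95% interval 0.60 to 1.36) and below them in replicate 2 (−0.64, −1.31 to −0.12), with intervals over blocks of 50 kb of 1 library, not over libraries. Trimming replicate 2 to as many top-scoring regions as replicate 1 left the ratio at −0.86 (−2.24 to −0.07, with 22 regions on chromosome 4). Chromosome 4 regions scored lower than those of the large arms in replicate 2 (median 0.485 against 0.531). A cut by score removes relatively more of them, so it cannot decide whether list length matters. Replicate 2 may have lost the weaker chromosome 4 regions: among replicate 1 regions 24 of the 44 with higher scores were shared, and 13 of the 44 with lower scores (odds ratio 2.86, two-sided Fisher's exact p = 0.0302). On the large arms 48.5% of the 4923 replicate 1 regions were shared, so regions were lost there likewise. On chromosome 4 it was 37 of 88 (95% Wilson interval 32.3 to 52.5%). Shared regions of the large arms also scored higher (median 0.661 against 0.590 for the others), so the test does not explain the opposite ratios. Of the replicate 2 regions, 29.3% of 8524 on the large arms had a replicate 1 partner, against 38 of 49 on chromosome 4. No biological explanation was tested.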
